A study of Homo sapiens with 12 samples.

How the data were processed

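The series holds RNA sequencing of 2 human triple-negative breast cancer lines, each as sensitive and as THZ1-resistant cells, with 3 vehicle-treated libraries per group and 12 in all. Samples were grouped by the cell line and phenotype in the labels. The labels number the replicates but do not say whether they are separate cultures, so p-values here measure the spread between the libraries of a group. Per the labels' protocols, RNA was isolated with TRIzol and paired-end Illumina reads were mapped to hg19, and the submitters' processing notes name DESeq2 and hg19. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be separated.

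The authors deposited 1 table per cell line. Per the file headers, each holds read counts per gene and library, which are whole numbers and not normalized. Each also holds the authors' FPKM values, which divide the counts by gene length and depth. From the values, the FPKM of the MDA-MB-231 table use the total of the listed counts as depth, while those of the MDA-MB-468 table use 1.18 to 1.27 times that total, so the authors' FPKM were not compared across tables. The MDA-MB-468 table also gives the authors' normalized signal per library, counts over 1 size factor, and the MDA-MB-231 table gives the authors' normalized signal as group means. Both tables give the authors' log2 fold change and the authors' p-value with its adjusted value. For genes with a mean count under 5, the median size of the deposited log2 fold change was 0.09 in the MDA-MB-231 table and 1.97 in the MDA-MB-468 table, so the deposited log2 values of low genes are not on a common footing. The adjusted p-value in the deposited tables is missing for 9122 genes of MDA-MB-231 and exactly 1 for 4300 genes of MDA-MB-468.

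The MDA-MB-231 table lists 28701 genes and the MDA-MB-468 table lists 27722, with 0 that lack a name and 0 with no read in any library. Both tables share 23920 genes, of which 95.46% have the same coordinates and 31.3% the same length. In a GRCh37 annotation, 27475 and 26716 of the gene IDs were found, and 99.99% of these overlapped their locus in each table. Depth was 18.8 to 26.4 M counts in MDA-MB-231 and 19.3 to 42.2 M in the MDA-MB-468 table. Counting intervals are at the 95% level, a group with 0 reads was given a floor of 3 counts over the group, and these cover counting error only.

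Counts were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM normalization and the quasi-likelihood test, separately in each line, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The design and the filter, lists and alternatives named below were chosen before the data were examined, except where a later choice is stated. CPM use TMM-scaled library sizes. Of 39 gene lists, those with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists, with medians of member log2 differences beside them. Medians with members of 0 reads set to their bound were the same to 2 decimals in the tested lists. The overlap of calls with at least a 2-fold change was tested with a one-sided Fisher's exact test per direction. The difference of the effects was tested as an interaction in 1 fit of all 12 libraries over the genes in both tables. Levels compared between the tables come from counts that the authors made separately and that were normalized together here.

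Genes named in the text follow a fixed rule. In each line these are the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the threshold, with no overlap between the 3 values of each group (chance gives 10% of genes without overlap) and a mean of at least 100 counts in the higher group, leaving out unnamed clones. From each list come up to 4 members past the threshold with the smallest p and that mean count, and ABCB1, ABCG2, CDK7, INHBA, TGFB1, TGFB2, TGFBR1, TGFBR2, SMAD3, SMAD4, CDH1, VIM and MYC were taken whatever their result. Some genes and 1 list that this rule brings in are not reported here. Across lines these are the 10 genes with the largest change in the same direction and the 10 with the largest opposite change. RB1, MTAP and the genes of the label check were chosen after their values were seen.

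Alternatives were RLE size factors, no filter and a stricter filter (a mean of at least 10 counts), DESeq2 1.42.0 and limma-voom, an adjusted p under 0.01, a test against a 1.5-fold change, protein-coding genes alone, the authors' deposited adjusted p, a replicate block, each library left out in turn, fry and camera with an estimated correlation. The comparison of the libraries labelled resistant MDA-MB-468 with sensitive MDA-MB-231 was added after the data were seen. The steps were tested on simulated counts with 200 changed genes. For MDA-MB-231, with 15284 genes, 85% of 2-fold and 93% of 4-fold changes were recovered, with 6.81% false among the calls. For MDA-MB-468, with 16133 genes, these were 79%, 94% and 5.46%. For the interaction, with 14301 genes, 93% of 4-fold changes were recovered with 4.12% false. A planted list was found with the preset and with the estimated correlation in both lines, and 0 and 1 of 20 unchanged lists were called with the preset. The simulated genes were drawn independently, so these counts do not show how the preset behaves with correlated genes. On the real counts, splits that mixed sensitive and resistant libraries still called up to 10 lists in MDA-MB-231 and up to 11 in MDA-MB-468. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.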

Results

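Gene expression was measured by RNA sequencing in MDA-MB-231 and MDA-MB-468, 2 human triple-negative breast cancer cell lines. Parental cells, called sensitive, were set beside cells selected for resistance to THZ1, a covalent inhibitor of the transcriptional kinase CDK7. The labels give a selection with rising doses over 2 months, up to 250 nM. All 12 libraries came from vehicle-treated cells, with RNA taken 48 h after treatment, and each of the 4 groups had 3 libraries. The MDA-MB-231 libraries held 18.8 to 26.4 M gene counts and the libraries of the MDA-MB-468 table held 19.3 to 42.2 M. The series title sets the question of whether signalling of the TGF-β family goes with resistance to CDK7 inhibition through multidrug transporters. In the values below, CPM are counts per M reads after normalization with their SD, n = 3 per group, and log2 differences carry their standard error after ±.

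Genes whose presence or absence is known for each line are given first, as a check of the labels; they were chosen after their values had been seen. SMAD4, the shared partner of the receptor-activated SMADs and a gene that MDA-MB-468 cells are known to have lost, had 5, 3 and 7 counts in the sensitive MDA-MB-468 libraries. In the libraries labelled resistant MDA-MB-468 it had 760, 709 and 904 counts. RB1, the retinoblastoma gene, also known to be disrupted in MDA-MB-468, had 42, 52 and 40 counts against 953, 690 and 1082. CDKN2A, the p16 gene that lies in a deleted region of MDA-MB-231, had 0 counts in each library labelled resistant MDA-MB-468 and 4511, 7547 and 5573 in the sensitive MDA-MB-468 libraries. CDKN2B and MTAP, its neighbours, also had 0 counts in each library labelled resistant MDA-MB-468. Across genes, log2 CPM of these 3 libraries correlated at r = 0.962 to 0.974 with the MDA-MB-231 libraries and at 0.878 to 0.884 with the sensitive MDA-MB-468 libraries. Of 1413 genes that separated the sensitive lines at least 32-fold, 85.6% were nearer to sensitive MDA-MB-231 in the libraries labelled resistant MDA-MB-468, and 93.1% were in resistant MDA-MB-231. Every direction given below for the libraries labelled resistant MDA-MB-468 against sensitive MDA-MB-468 rests on a comparison in which these line-specific genes differ as well. These joint values set 2 tables side by side that the authors counted separately.

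**Figure D1:**
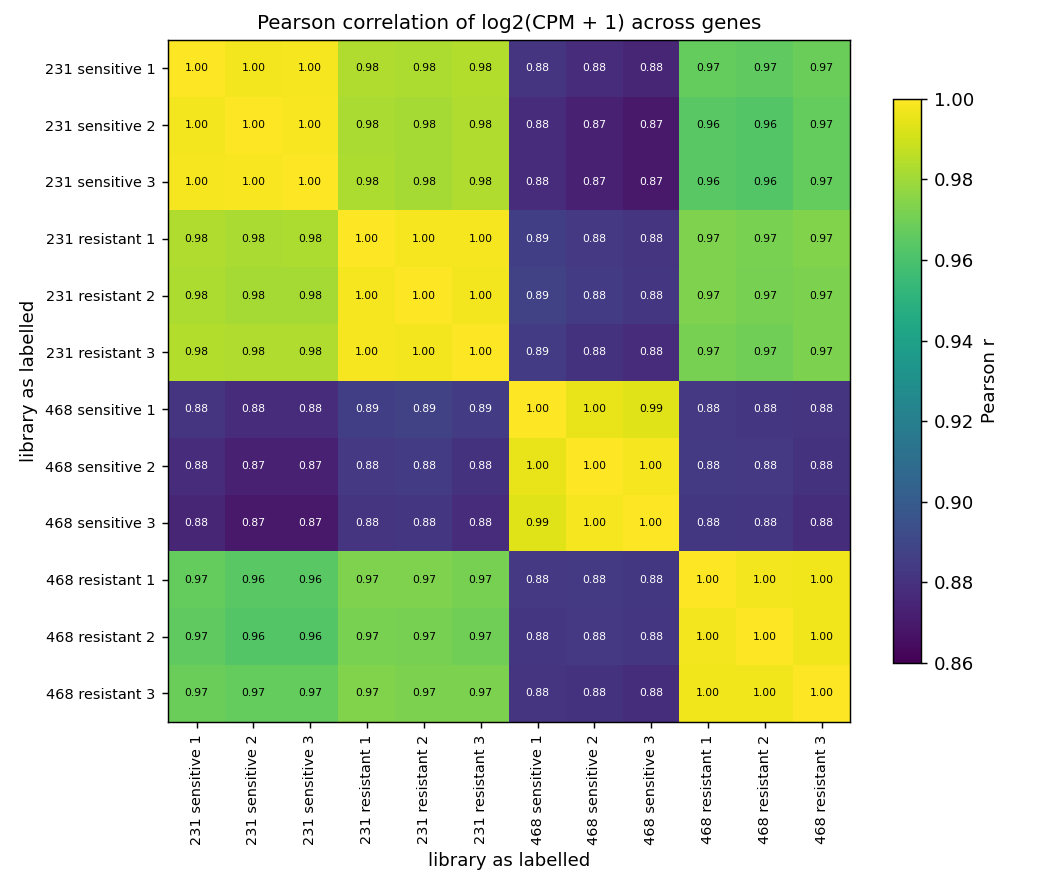
Pearson correlation of log2(CPM + 1) across the genes in both tables, for each pair of the 12 libraries as labelled. The libraries labelled resistant MDA-MB-468 correlate at 0.962 to 0.974 with the MDA-MB-231 libraries and at 0.878 to 0.884 with sensitive MDA-MB-468.

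In resistant MDA-MB-231 cells, the drug efflux pump gene ABCG2 was 9.93-fold higher than in sensitive cells, at 66.4 ± 5.11 against 6.65 ± 0.441 CPM. INHBA, which encodes the subunit of activin A, was 3.46-fold higher, at 57.6 ± 3.46 against 16.6 ± 1.68 CPM. Most inflammatory, interferon-response and antigen-presentation genes were higher, basal keratins appeared, and most genes of cholesterol synthesis were lower. The inflammatory, interferon, antigen-presentation and cholesterol lists passed camera with the preset correlation, and 0 of 37 lists passed with an estimated one. The neutrophil lipocalin gene LCN2 was 291-fold higher (451 ± 15.5 against 1.54 ± 0.332 CPM) and the complement gene C3 was 110.2-fold higher (875 ± 28.5 against 7.99 ± 0.988 CPM). ABCG2, INHBA, LCN2 and C3 were each higher in 3 of 3 resistant libraries than in any sensitive one.

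Among the 10 protein-coding genes that rose most by the rule for named genes, KRT6A, a keratin of stratified epithelium, had 0 reads in sensitive cells and was at least 240-fold higher. Its reads may be shared with near-identical keratin genes. KRT5, the basal keratin that pairs with KRT14, had a ratio of 395 (95% counting interval 109 to 3260), and PIGR, the receptor that carries polymeric immunoglobulins across epithelium, had a ratio of 530 (95% counting interval 146 to 4380). SLPI, a secreted protease inhibitor, was 149-fold higher. ABCA6 was 95.9-fold higher, the chemokine gene CCL5 84.7-fold, PDZK1IP1 82.2-fold and the retinol transporter gene STRA6 64.7-fold. Among the 10 that fell most, the phosphodiesterase gene PDE1C had 0 reads in resistant cells and was at least 614-fold lower. ACSS3 was at least 162-fold lower, RHOJ at least 140-fold lower and NRK at least 104-fold lower, each with 0 reads in resistant cells. NEGR1 was 208-fold lower, PPAPDC1A 129-fold and the kinase gene DAPK1 119-fold. The ratio of sensitive to resistant was 325 (95% counting interval 57.9 to 12900) for PKIA, 225 (95% counting interval 76.7 to 1090) for the cadherin gene FAT3 and 152 (95% counting interval 51.6 to 739) for ZNF521.

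Of the multidrug efflux transporters, 8 were tested in MDA-MB-231, 4 were higher, 2 lower and 2 not past the threshold, and the list as a whole did not pass (camera, adjusted p = 0.165; median log2 difference 0.25). ABCG2 changed by 3.31 ± 0.094 on the log2 scale and was the member with the smallest p (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.47e-15). In the deposited coordinates of build hg19, ABCG2 (ENSG00000118777) lies on chromosome 4 from 89011416 to 89152474. ABCC3 was 5.24-fold higher, ABCC10 1.19-fold higher and ABCC5 1.4-fold lower. ABCB1, which encodes P-glycoprotein, had 0 to 2 counts per library and was too low to test. Of 24 other ABC transporters, 10 were higher and 5 lower (camera, adjusted p = 0.0939; median 0.18). Among them ABCA7 was 3.27-fold higher, ABCA10 18-fold higher and the peptide transporter gene TAP1 1.83-fold higher.

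The lists of the TGF-β family did not pass as wholes in MDA-MB-231, while single members changed strongly. Of 17 ligands, 7 were higher and 5 lower (camera, adjusted p = 0.576). INHBA (ENSG00000122641, chromosome 7 from 41724712 to 41742706) changed by 1.79 ± 0.088 on the log2 scale (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.32e-12). The stress ligand gene GDF15 was 5.44-fold higher, BMP1 1.8-fold higher and GDF11 1.6-fold lower. TGFB1 differed by 0.23 ± 0.067 (adjusted p = 0.00795, edgeR), and without sensitive replicate 2 by 0.19 (adjusted p = 0.0559). TGFB2 differed by -0.11 ± 0.068 and did not pass (adjusted p = 0.197, edgeR). Of 12 receptors, 2 were higher and 6 lower (camera, adjusted p = 0.308). TGFBR2 was 1.33-fold lower, TGFBR1 1.21-fold lower, BMPR2 1.31-fold lower and ACVR2B 2.05-fold lower, while the pseudoreceptor gene BAMBI was 1.99-fold higher. Of 16 SMADs and regulators, 5 were higher and 6 lower (camera, adjusted p = 0.934). The inhibitory SMAD6 was 3.49-fold higher, SMAD3 1.26-fold higher, SMAD5 1.49-fold lower and the ubiquitin ligase gene SMURF2 1.51-fold lower. SMAD4 differed by -0.07 ± 0.082 and did not pass (adjusted p = 0.495, edgeR). Of 12 antagonists and latency proteins, 2 were higher and 8 lower (camera, adjusted p = 0.112). The activin antagonist gene FST was 5.58-fold lower, FSTL1 3.92-fold lower and HTRA1 7.65-fold lower, while LTBP3 was 6.77-fold higher.

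Of 26 SMAD2/3 target genes in MDA-MB-231, 12 were higher and 6 lower (camera, adjusted p = 0.18; median log2 difference 0.19). ANGPTL4 was 10.6-fold higher, TGFBI 3.1-fold and the fibronectin gene FN1 2.66-fold higher, while CTGF was 6.04-fold lower. Of 10 BMP target genes, 7 were higher and 3 lower (camera, adjusted p = 0.0691; median 1.05). ID1 was 2.48-fold higher, ID2 3.73-fold and ID3 3.63-fold.

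Epithelial markers rose in resistant MDA-MB-231: of 17 tested, 16 were higher, 0 lower and 1 not past (camera, adjusted p = 2.38e-07; median 1.43). With an estimated correlation the adjusted p was 0.152. The E-cadherin gene CDH1 was 18.6-fold higher, at 7.09 ± 0.581 against 0.376 ± 0.102 CPM, the transcription factor gene ELF3 11.5-fold higher and the tight-junction gene OCLN 2.83-fold higher. Of 18 mesenchymal markers, 8 were higher and 7 lower (camera, adjusted p = 0.934), with CDH11 2.72-fold and TNC 2.32-fold higher and AXL 2.28-fold and VIM 1.79-fold lower. Of 8 luminal markers, 5 were higher and 2 lower (camera, adjusted p = 0.54). SPDEF was 75.8-fold lower, and XBP1 1.51-fold, ERBB3 2.42-fold and KRT18 1.43-fold higher.

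Inflammatory genes formed the clearest block in resistant MDA-MB-231. All 22 tested NF-κB targets and cytokines were higher (camera, adjusted p = 1.23e-12; median 2.29; adjusted p = 0.134 with an estimated correlation). CXCL1 was 34.1-fold higher, IL1B 46.3-fold, IL8 8.64-fold and the adhesion gene ICAM1 5.14-fold. Of 24 interferon-response genes, 23 were higher and 1 was not past (camera, adjusted p = 1.75e-10; median 1.17; adjusted p = 0.134 with an estimated correlation). OASL was 9.33-fold higher, ISG15 4.18-fold, IFI27 3.65-fold and IFIT3 2.43-fold. Of 21 antigen-presentation genes, 20 were higher and 1 was not past (camera, adjusted p = 2.03e-11; median 1.38; adjusted p = 0.229 with an estimated correlation). HLA-F was 15.9-fold higher, HLA-B 5.73-fold, HLA-DPA1 6.18-fold and CD74 4.32-fold. Reads can be split between the similar HLA genes, so their single values are uncertain.

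Of 27 collagens and laminins in MDA-MB-231, 17 were higher and 7 lower (camera, adjusted p = 0.0108; median 0.58; adjusted p = 0.495 with an estimated correlation). The basement-membrane genes COL4A5 and COL4A6 were 11.6-fold and 20.7-fold higher, COL6A2 2.8-fold higher and COL13A1 3.19-fold lower. Of 19 NRF2 target genes, 16 were higher and 3 lower (camera, adjusted p = 0.0019; median 0.41; adjusted p = 0.229 with an estimated correlation). The ferritin genes FTH1 and FTL were 2.24-fold and 2.03-fold higher and ME1 1.97-fold higher, while the cystine transporter gene SLC7A11 was 2.2-fold lower. Genes of cholesterol synthesis fell, with 16 of 18 lower, 0 higher and 2 not past (camera, adjusted p = 5.19e-07; median -0.71; adjusted p = 0.152 with an estimated correlation). INSIG1, which holds back the activation of SREBP, was 4.61-fold lower, STARD4 5.14-fold and the regulator gene SREBF2 2.39-fold. The list of cyclin D and CDK inhibitor genes also holds CDK4, CDK6 and RB1. Of its 11 tested members, 9 were lower and 1 higher (camera, adjusted p = 0.0108, median -0.49, adjusted p = 0.229 with an estimated correlation). The lower members included both cyclins and inhibitors: CCND1 was 1.88-fold lower, CCND3 1.41-fold, CDKN1C 2.23-fold and CDKN2D 2.22-fold. Of 18 early response factors, 9 were lower and 3 higher (camera, adjusted p = 0.0313; median -0.52; adjusted p = 0.6 with an estimated correlation). Without resistant replicate 3 that list did not pass (adjusted p = 0.0773). DUSP4, DUSP5 and DUSP6, phosphatases that act on MAP kinases, were 2.06-fold, 2.37-fold and 2.22-fold lower and IER3 1.91-fold higher. Of 12 replication-dependent histone genes, 9 were lower and 1 higher (camera, adjusted p = 0.00239; median -0.98; adjusted p = 0.229 with an estimated correlation), among them HIST1H2AC, 2.01-fold lower, HIST1H2BD, 2.01-fold, HIST1H2BK, 1.72-fold, and HIST1H1C, 1.56-fold. Histone genes are near-identical and mostly lack poly(A) tails, so their counts are uncertain.

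CDK7 itself was 1.3-fold higher in resistant MDA-MB-231, at 58.9 ± 2.41 against 45.4 ± 1.67 CPM (edgeR, adjusted p = 0.000185). Of 9 genes of TFIIH and the CDK-activating kinase, 4 were higher and 1 lower (camera, adjusted p = 0.578), with CCNH 1.22-fold lower and GTF2H1 1.17-fold higher. GTF2H1 did not pass without sensitive replicate 2 (adjusted p = 0.0504), and GTF2H2, 1.37-fold higher, has a near-identical copy. Of 17 other transcriptional kinases and partners, 2 were higher and 6 lower (camera, adjusted p = 0.12), with POLR2A 1.67-fold, CDK19 1.66-fold and MED13 1.37-fold lower. The list of transcription factors studied with CDK7 in triple-negative cells also holds the receptor gene EGFR. Of its 10 tested members, 3 were higher and 6 lower (camera, adjusted p = 0.535). TFAP2C was 2.52-fold higher, and ETS1 1.87-fold and SOX9 1.73-fold lower. MYC differed by -0.15 ± 0.06 (adjusted p = 0.0365, edgeR), a call lost without any of 5 single libraries (sensitive replicates 1, 2 and 3 and resistant replicates 1 and 3, adjusted p = 0.0516 to 0.137). Of 30 cell-cycle genes, 7 were higher and 15 lower (camera, adjusted p = 0.176), with the proliferation marker MKI67 3.07-fold lower, FOXM1 1.71-fold and MCM2 1.84-fold lower and CCNE1 1.77-fold higher.

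The other lists did not pass in MDA-MB-231. Of 13 BCL2-family genes, 5 were higher and 5 lower (camera, adjusted p = 0.755), with BIK 8.33-fold higher and BCL2 2.52-fold lower. Of 17 xenobiotic-metabolism genes, 10 were higher and 5 lower (adjusted p = 0.166, camera), with CYP1B1 4.86-fold and MGST1 3.77-fold higher. Of 9 stem-like markers, 4 were higher and 5 lower (camera, adjusted p = 0.934), with ALDH1A3 7.8-fold higher. Of 16 integrins, 6 were higher and 6 lower (camera, adjusted p = 0.934), with ITGA1 5.17-fold higher and ITGB2 8.05-fold lower. Of 20 matrix proteases, 9 were higher and 8 lower (camera, adjusted p = 0.783), with MMP15 4.95-fold higher and ADAMTS1 10.2-fold lower. Of 22 hypoxia and glycolysis genes, 4 were higher and 11 lower (camera, adjusted p = 0.154), with CA9 11.2-fold higher and BNIP3 2.3-fold lower. Of 19 unfolded-protein and amino-acid stress genes, 8 were higher and 6 lower (camera, adjusted p = 0.737), with the serine-synthesis gene PHGDH 9.82-fold lower and PDIA4 2.13-fold higher. Of 20 receptor tyrosine kinases, 4 were higher and 8 lower (camera, adjusted p = 0.18), with KDR 4.51-fold lower. Of 13 WNT genes, 3 were higher and 7 lower (camera, adjusted p = 0.18), with FZD8 8.82-fold lower and WNT10A 14.8-fold higher.

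The lists of RNA-quality and fibroblast markers did not pass in MDA-MB-231. Of 13 mitochondrial transcripts, 1 was higher and 4 lower (camera, adjusted p = 0.496), and of 31 ribosomal protein genes, 14 were higher and 7 lower (camera, adjusted p = 0.519). Both classes share reads with pseudogenes. Of 6 fibroblast markers, 2 were higher and 3 lower (camera, adjusted p = 0.934). Of 3 leukocyte markers, 2 were higher, CD14 among them (6.57-fold higher), and of 4 endothelial markers, 1 was higher and 3 lower, with ESAM 4.2-fold lower; these lists were too short for a test. Adjusted over the list alone, the counts in MDA-MB-231 were the same except for other ABC transporters (12 higher), SMAD2/3 targets (13 higher, 7 lower), transcriptional kinases (1 higher), cyclin D and CDK inhibitors (10 lower), interferon response (24 higher), collagens and laminins (18 higher, 8 lower), histones (11 lower) and fibroblast markers (3 higher).

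**Figure D2:**
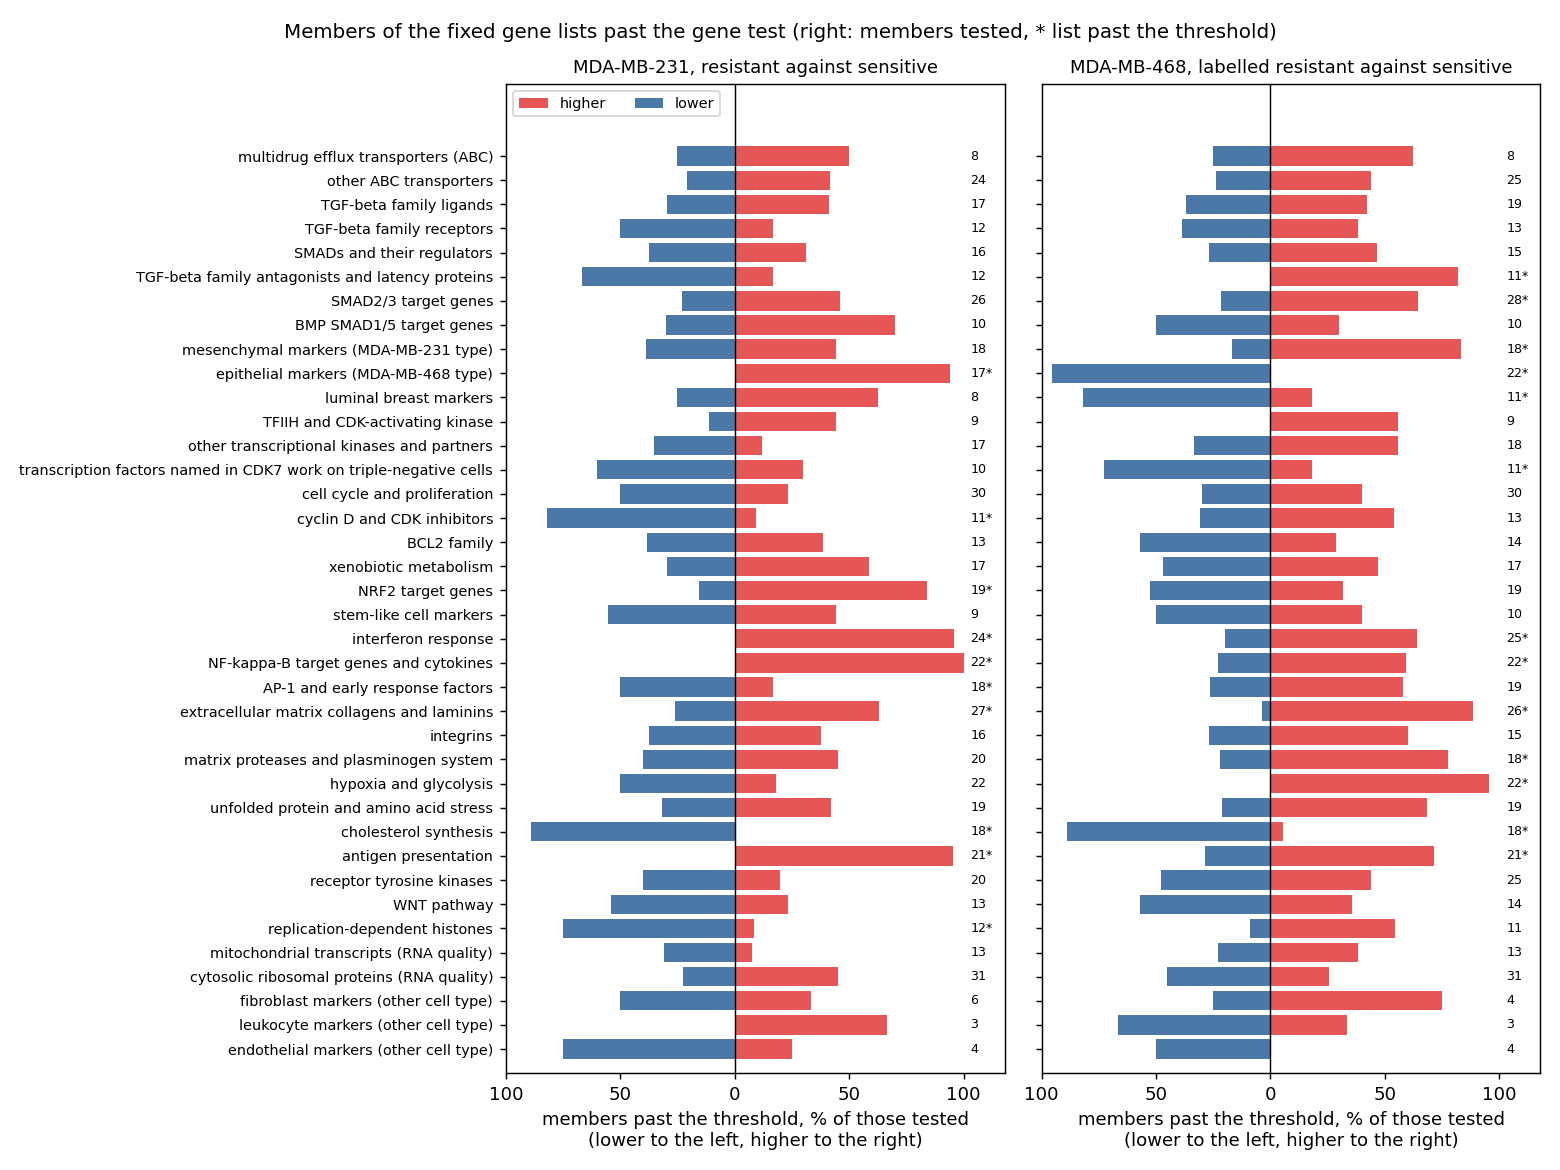
Share of tested list members that were higher (to the right, red) or lower (to the left, blue) past the gene test in each comparison, as percent of the members tested. The number at the right is the number tested, and an asterisk marks lists past the threshold, 10 in MDA-MB-231 and 13 in MDA-MB-468 as labelled.

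Across all genes, 8595 of 15284 tested in MDA-MB-231 passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 4222 higher and 4373 lower in resistant cells. Of these, 2037 changed at least 2-fold, 1082 higher and 955 lower. Of 37 lists, 10 passed with the preset correlation, 6 higher and 4 lower, and 0 with an estimated correlation, where 28 passed by fry. Mean and median log2 differences had opposite signs for ligands, SMADs, luminal markers, CDK7-linked transcription factors, integrins, stress genes and fibroblast markers, none of them past the threshold.

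In the libraries labelled resistant MDA-MB-468, most genes of a mesenchymal type were higher than in sensitive MDA-MB-468 cells and most epithelial genes lower. Neither list passed with an estimated correlation (camera, both adjusted p = 0.275). The collagen genes COL5A1 and COL6A1 had 0 reads in sensitive cells and were at least 50200-fold and at least 16200-fold higher. The intermediate-filament gene VIM was 1033-fold higher, at 1573 ± 34.1 against 1.51 ± 0.29 CPM, and the calgranulin gene S100A9 had 0 reads in the libraries labelled resistant MDA-MB-468 and was at least 30500-fold lower. ABCG2 was higher by 9.90 ± 0.287 on the log2 scale, at 52.7 ± 2.6 against 0.0424 ± 0.047 CPM, with 1, 4 and 0 counts in the sensitive libraries. In the same comparison SMAD4 and RB1 were 236-fold and 30.9-fold higher, and CDKN2A was at least 3790-fold lower with 0 reads in the libraries labelled resistant.

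Among the 10 protein-coding genes with the largest rise, the ratio for EEF1A2, an elongation factor gene, was 69000 (95% counting interval 12400 to 2730000). APCDD1L was at least 5090-fold higher, the cadherin gene CDH11 at least 4410-fold, SLC17A9 at least 4290-fold, LAPTM5 at least 4040-fold, BCAT1 at least 4020-fold, HTRA3 at least 3500-fold and PRKCDBP at least 3490-fold, each with 0 reads in sensitive MDA-MB-468. Among those with the largest fall, the kallikrein gene KLK5 was at least 10600-fold lower, VTCN1 at least 6610-fold, OLFM4 at least 5890-fold, S100A7 at least 5880-fold, LAD1 at least 5770-fold, CALML5 at least 5300-fold, WNT6 at least 4890-fold and PROM1 at least 4370-fold, each with 0 reads in the libraries labelled resistant.

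Of 8 multidrug efflux transporters tested in this comparison, 5 were higher and 2 lower (camera, adjusted p = 0.219; median 1.75). ABCC1 was 3.68-fold higher, ABCC3 3.07-fold higher and ABCC5 2.24-fold lower. ABCB1 had 0 to 1 counts in the libraries labelled resistant MDA-MB-468 and 1 to 9 in sensitive MDA-MB-468, too few to test. Of 25 other ABC transporters, 11 were higher and 6 lower (camera, adjusted p = 0.197), with ABCA1 460.4-fold higher and ABCA4 8.84-fold lower. Of 19 ligands, 8 were higher and 7 lower (camera, adjusted p = 0.827). INHBA was 7.12-fold higher, GDF15 60.3-fold, BMP4 15.6-fold, TGFB1 3.09-fold and TGFB2 2.36-fold higher, and BMP7, with 0 reads in the libraries labelled resistant, was at least 775-fold lower. Of 13 receptors, 5 were higher and 5 lower (camera, adjusted p = 0.706), with TGFBR2 9.05-fold and TGFBR1 4.7-fold higher and ENG 8.94-fold lower. Of 15 SMADs and regulators, 7 were higher and 4 lower (camera, adjusted p = 0.197), with SMAD3 6.31-fold higher. Antagonists and latency proteins were higher than in sensitive MDA-MB-468 in 9 of 11 and lower in 0 (camera, adjusted p = 0.000623, median 3.56, adjusted p = 0.275 with an estimated correlation). THBS1 was 26.9-fold, NOG 63.7-fold and FSTL3 15.5-fold higher. Against sensitive MDA-MB-231, 5 of 12 antagonists and latency proteins were higher and 7 lower (camera, adjusted p = 0.571). Of 28 SMAD2/3 targets, 18 were higher and 6 lower (camera, adjusted p = 0.00313; median 2.56; adjusted p = 0.371 with an estimated correlation), with TGFBI 131-fold and FN1 27-fold higher. Of 10 BMP targets, 3 were higher and 5 lower (camera, adjusted p = 0.827), with ID1 13.6-fold higher and ID2 52.6-fold lower.

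Of 18 mesenchymal markers, 15 were higher and 3 lower in the libraries labelled resistant MDA-MB-468 (camera, adjusted p = 0.000243; median 4.27; adjusted p = 0.275 with an estimated correlation), with the receptor gene AXL 1103-fold and CAV1 56.1-fold higher. Of 22 epithelial markers, 21 were lower and 0 higher (camera, adjusted p = 3.81e-08; median -4.36; adjusted p = 0.275 with an estimated correlation). KRT5 was 6275-fold lower, ESRP1 454-fold, ST14 417-fold and CDH1 3.88-fold lower. These lists were fixed beforehand as markers of the MDA-MB-231 type and the MDA-MB-468 type, so they also mark the difference between the lines. Of 11 luminal markers, 9 were lower and 2 higher (camera, adjusted p = 0.0392; median -1.46; adjusted p = 0.28 with an estimated correlation), with SPDEF 43.8-fold and ERBB3 21.9-fold lower. That call was lost without resistant replicate 2 (adjusted p = 0.0552) and with no filter on low counts (0.0586). Of 26 collagens and laminins, 23 were higher and 1 lower (camera, adjusted p = 3.81e-08, median 4.27, adjusted p = 0.28 with an estimated correlation). LAMA3 was 73.1-fold and COL13A1 76.5-fold higher. Of 18 matrix proteases, 14 were higher and 4 lower (camera, adjusted p = 0.000876; median 4.57; adjusted p = 0.275 with an estimated correlation), with ADAM8 100.3-fold and PLAU 54.9-fold higher and MMP7 321-fold lower. Of 22 hypoxia and glycolysis genes, 21 were higher and 0 lower (camera, adjusted p = 3.58e-06, median 1.73, adjusted p = 0.28 with an estimated correlation). SLC2A3 was 590.5-fold, P4HA1 14.2-fold, ENO2 11.4-fold and BNIP3 5.71-fold higher.

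Cholesterol genes were lower than in sensitive MDA-MB-468 in 16 of 18 and higher in 1 (camera, adjusted p = 0.000623, median -1.49, adjusted p = 0.275 with an estimated correlation). FDFT1 was 6-fold lower, SQLE 5.64-fold and DHCR7 6.3-fold. Of 25 interferon-response genes, 16 were higher and 5 lower (camera, adjusted p = 0.0253; median 1.35; adjusted p = 0.321 with an estimated correlation), with IFI27 185-fold and OASL 31-fold higher. Of 22 NF-κB targets and cytokines, 13 were higher and 5 lower (camera, adjusted p = 0.0261; median 0.69; adjusted p = 0.321 with an estimated correlation), with IL6 215-fold higher. Of 21 antigen-presentation genes, 15 were higher and 6 lower (camera, adjusted p = 0.0199; median 0.56; adjusted p = 0.594 with an estimated correlation), with CD74 1150-fold and HLA-DRA 1510-fold higher. Of 11 members of the list of transcription factors studied with CDK7, EGFR included, 8 were lower and 2 higher (camera, adjusted p = 0.0478, median -2.50, adjusted p = 0.321 with an estimated correlation). FOXC1 was 7.47-fold, LMO4 7.43-fold and ELF3 8.86-fold lower, and FOSL1 51.3-fold higher. That call was lost without any of 5 single libraries (sensitive replicates 1, 2 and 3 and resistant replicates 1 and 2, adjusted p = 0.0505 to 0.0554). CDK7 was 1.56-fold higher, at 39.6 ± 2.67 against 25.4 ± 1.28 CPM, and MYC differed by 0.08 ± 0.09 and did not pass (edgeR, adjusted p = 0.452).

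The other lists did not pass in this comparison. TFIIH genes were higher in 5 of 9 and lower in 0 (camera, adjusted p = 0.196), with GTF2H3 4.26-fold higher, and other transcriptional kinases higher in 10 of 18 and lower in 6 (0.699), with CDK19 3.1-fold lower. Cell-cycle genes were higher in 12 of 30 and lower in 9 (camera, adjusted p = 0.827), with E2F2 7.08-fold lower. Members of the list of cyclin D and CDK inhibitor genes were higher in 7 of 13 and lower in 4 (camera, adjusted p = 0.497). That list holds RB1, CDKN2A and CDKN2B, genes of the label check. BCL2-family genes were higher in 4 of 14 and lower in 8 (camera, adjusted p = 0.601), with BCL2L1 3.88-fold higher. Xenobiotic-metabolism genes were higher in 8 of 17 and lower in 8 (camera, adjusted p = 0.942), with AKR1B1 6.96-fold higher. NRF2 targets were higher in 6 of 19 and lower in 10 (camera, adjusted p = 0.414), with FTL 12.4-fold higher and AKR1C1 and AKR1C2, which share reads, 20.1-fold and 289-fold lower. Stem-like markers were higher in 4 of 10 and lower in 5 (camera, adjusted p = 0.489), with NOTCH3 297-fold lower. Early response factors were higher in 11 of 19 and lower in 5 (camera, adjusted p = 0.0541), with DUSP6 28.6-fold higher, and this list passed without sensitive replicate 3 (0.0439), resistant replicate 1 (0.0474) or resistant replicate 3 (0.0494). Integrins were higher in 9 of 15 and lower in 4 (camera, adjusted p = 0.0917), with ITGA5 37.8-fold higher. Stress genes were higher in 13 of 19 and lower in 4 (camera, adjusted p = 0.075), with PHGDH 225-fold lower and HSPA5 9.29-fold higher. Receptor tyrosine kinases were higher in 11 of 25 and lower in 12 (camera, adjusted p = 0.706), with FGFR4 20.8-fold lower. WNT genes were higher in 5 of 14 and lower in 8 (camera, adjusted p = 0.45), with DKK1 74.6-fold higher and SFRP1 412-fold lower. Histone genes were higher in 6 of 11 and lower in 1 (camera, adjusted p = 0.348), with HIST2H2AC 8.33-fold higher.

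Mitochondrial transcripts were higher in 5 of 13 and lower in 3 (camera, adjusted p = 0.521), and ribosomal protein genes higher in 8 of 31 and lower in 14 (0.45). Of 4 fibroblast markers, 3 were higher and 1 lower, with COL6A3 243-fold higher. Of 3 leukocyte markers, 1 was higher and 2 lower, with CD14 12.6-fold lower, and of 4 endothelial markers, 0 were higher and 2 lower. These 3 lists were too short for a test. Adjusted over the list alone, the counts were the same for every list named in this comparison. Sensitive MDA-MB-468 replicate 1 stood apart from its group, with 7.81% of counts from mitochondrial genes against 5.76% and 5.52%.

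Across all genes, 12007 of 16133 tested passed in MDA-MB-468 as labelled (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 5913 higher and 6094 lower. Of these, 7188 changed at least 2-fold, 3461 higher and 3727 lower. Of 36 lists, 13 passed with the preset correlation, 9 higher and 4 lower, and 0 with an estimated correlation, where 31 passed by fry. Mean and median had opposite signs for ligands, cell-cycle genes, cyclin D and CDK inhibitors, xenobiotic metabolism and receptor tyrosine kinases, none past the threshold. With sensitive MDA-MB-231 as the reference, a comparison chosen after the data were seen, 10718 of 15091 genes passed in the libraries labelled resistant MDA-MB-468 and 3862 changed at least 2-fold, 1824 higher and 2038 lower.

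**Figure D3:**
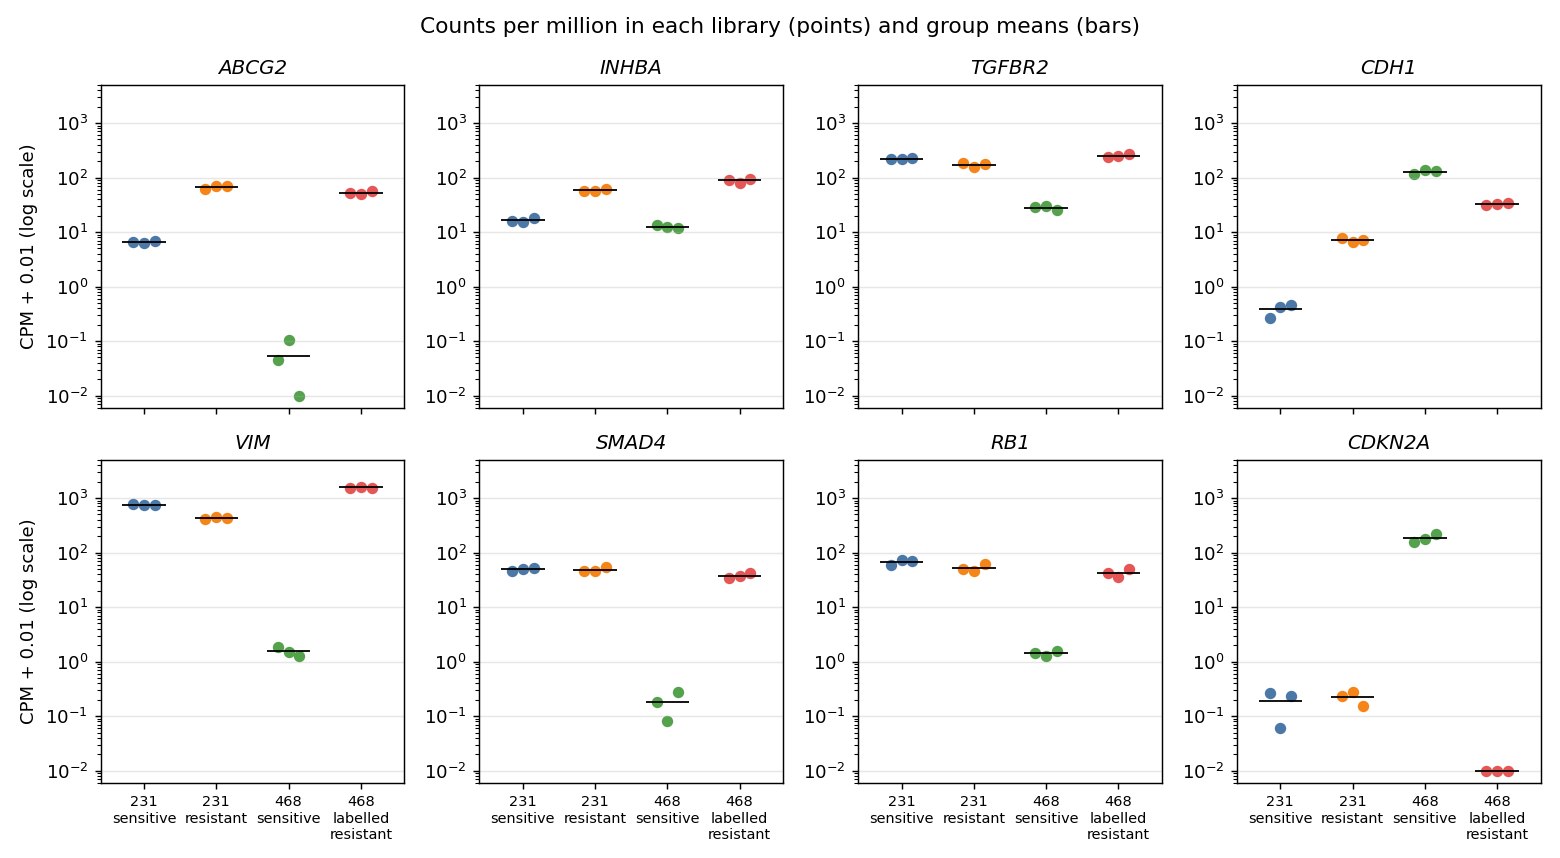
CPM plus 0.01 on a log axis for 8 genes, with a point per library, 3 per group, and a bar at the group mean. SMAD4 and RB1 are near the MDA-MB-231 level in the libraries labelled resistant MDA-MB-468, and CDKN2A has 0 counts there; ABCG2 and INHBA are higher in both resistant groups.

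Set against sensitive MDA-MB-231 in the same way, ABCG2 was higher by 3.09 ± 0.097 on the log2 scale in the libraries labelled resistant MDA-MB-468, at 54.4 against 6.47 CPM, beside 3.31 in resistant MDA-MB-231. INHBA was higher by 2.53 ± 0.092, ABCC3 by 3.06 ± 0.102, GDF15 by 4.02 ± 0.134 and C3 by 7.02 ± 0.098. CDH1 was higher by 6.53 ± 0.166 and VIM by 1.15 ± 0.066 and TGFB1 by 0.86 ± 0.073. SMAD4 changed by -0.31 ± 0.09. CDK7 differed by -0.09 ± 0.082 and did not pass (edgeR, adjusted p = 0.325).

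In the comparisons of both lines as labelled, ABCG2, INHBA, GDF15 and ABCC3 were higher. The list of cholesterol genes was lower in each, in 16 of 18 members, but did not pass with an estimated correlation (camera, adjusted p = 0.152 and 0.275). Set against sensitive MDA-MB-231, the libraries labelled resistant MDA-MB-468 had 11 of 18 cholesterol genes lower and 6 higher (camera, adjusted p = 0.402). Among 14301 genes tested in both, 340 were at least 2-fold higher in both, against 212.2 for independent lists (Fisher's exact test, one-sided, p = 9.31e-23), and 209 were lower in both, against 126.4 (p = 4.34e-15). Opposite changes were as frequent by the same Fisher's exact test: 336 genes were higher in resistant MDA-MB-231 and lower in the libraries labelled resistant MDA-MB-468 (167.6 for independent lists, Fisher's exact test, p = 3.35e-42) and 255 the reverse (160, p = 7.19e-17). Across genes, which are not independent replicates, the log2 differences correlated at Pearson r = 0.004 and Spearman rho = -0.027. Of the 10 genes with the largest shared change, ABCA6 and the non-coding gene CTD-2532K18.2 were higher, and NRK, PDE1C, FAT3, SEMA3E, NGFR, RIMS2, ROBO1 and AGR2 lower. The axon-guidance receptor gene ROBO1 was 53-fold lower in resistant MDA-MB-231 and 252-fold lower in the libraries labelled resistant MDA-MB-468, and NGFR was 56.6-fold and at least 20.6-fold lower. ABCA6 was 95.9-fold and at least 134-fold higher. The Fisher p-values describe these gene sets and treat genes as independent, which they are not.

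Of the 10 genes with the largest opposite change, KRT5, SLPI, PIGR, S100A9, LAD1 and the kallikrein gene KLK10 were higher in resistant MDA-MB-231 and lower in the libraries labelled resistant MDA-MB-468. PPAPDC1A, MIR137HG, TSPAN8 and COX7B2 went the other way. SLPI was 149-fold higher in the first and 75.3-fold lower in the second, and PPAPDC1A 129-fold lower and at least 1550-fold higher. In 1 fit of all 12 libraries, the effect of resistance as labelled differed between the lines for 11455 of 16650 genes (edgeR, Benjamini-Hochberg adjusted p under 0.05), 68.8%, with 5745 more positive and 5710 more negative in MDA-MB-468. Since the libraries labelled resistant MDA-MB-468 lay with MDA-MB-231 on the genes that separate the lines, this test also contains the difference between the lines.

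**Figure D4:**
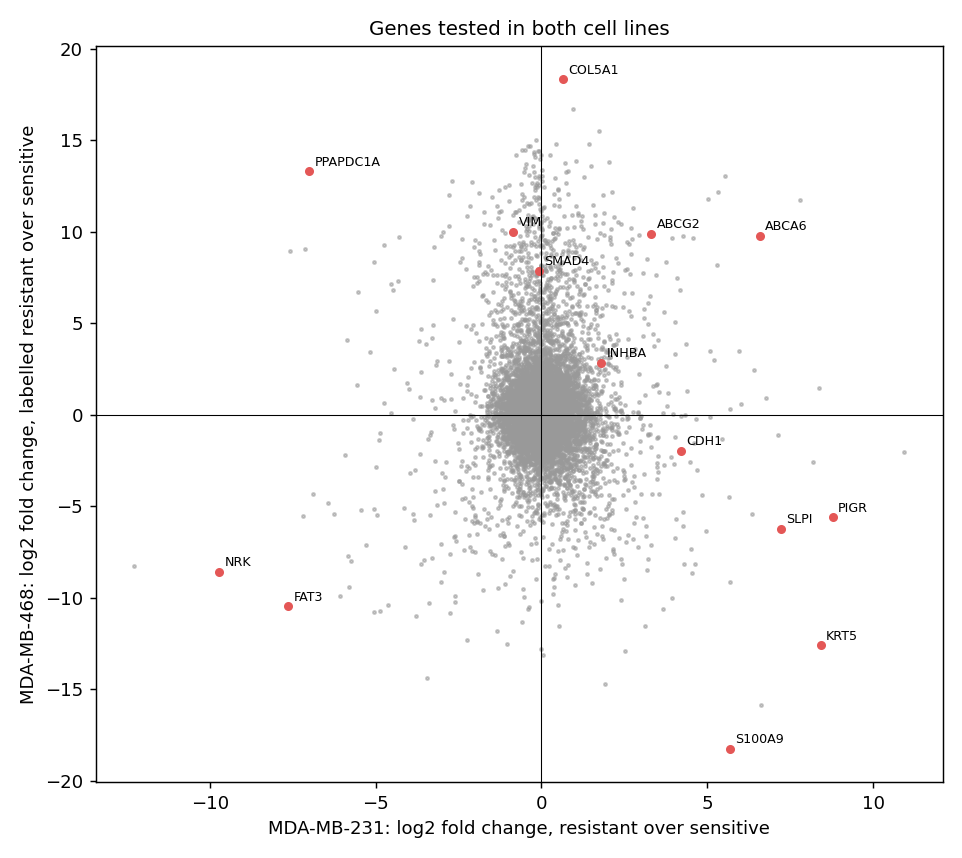
Fitted log2 fold change of each of 14301 genes in MDA-MB-231 (horizontal) and in MDA-MB-468 as labelled (vertical), with 14 genes named in red. The points show no common trend (Pearson r = 0.004), and values of genes with 0 to 3 reads in a group depend on the prior count.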

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

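The tests in this part were chosen after the results they concern had been seen, except the covariance with shared controls and the share of genes changed the same way, whose bounds were set before. The genes and lists below were singled out because the effect of resistance as labelled differed between the cell lines in the interaction test over 12 libraries.

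The interaction passed for 11455 genes. Of 100 splits of the libraries within the lines, 1 gave as many, the real one. Splits that mix the groups remove the effects within the lines and do not stand for equal effects in both, so they cannot decide on chance. The 10 splits that mixed MDA-MB-231 and kept the MDA-MB-468 groups gave 8731 to 9247 genes. The 11 splits of the reverse kind gave 134 to 278, and the 77 that mixed both lines gave 0. The highest other count, 11282, came from the split that keeps each group whole and exchanges the labels in 1 line. In MDA-MB-231 alone, 8595 genes passed in the real split and at most 0 in the others, and in MDA-MB-468 as labelled 12007 and at most 0. Those 3-against-3 comparisons have 10 splits each, of which 1 in each line gave as many genes, too few for a share under 0.05. For the gene lists, 2 of 10 splits in MDA-MB-231 gave 10 lists, the highest other count being 10 as well (sensitive replicates 1 and 2 with resistant replicate 2), and 1 of 10 in MDA-MB-468 gave 13, the highest other being 11.

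Among the TGF-β family and transporter genes, the log2 difference of effects, labelled MDA-MB-468 minus MDA-MB-231, was 6.52 for ABCG2, 0.99 for INHBA, 1.35 for TGFB1, 1.29 for TGFB2, 2.46 for TGFBR1, 3.54 for TGFBR2, 2.27 for SMAD3 and 7.90 for SMAD4. For the markers of cell state it was 10.80 for VIM, -6.23 for CDH1 and -21.09 for KRT5. For the other genes with opposite changes it was -13.51 for SLPI, -14.43 for PIGR, -14.90 for KLK10, -22.50 for LAD1, -23.92 for S100A9, 16.10 for TSPAN8, 12.24 for COX7B2, 20.23 for PPAPDC1A and 16.43 for MIR137HG. These are fitted values, and those of genes with 0 to 3 reads in a group depend on the prior count. The effects on the list of epithelial markers differed (camera, adjusted p = 2.66e-11; adjusted p = 0.0134 with an estimated correlation), and so did those on collagens and laminins (adjusted p = 5.25e-07; adjusted p = 0.145 with an estimated correlation).

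The first pattern weighed is that the libraries labelled resistant MDA-MB-468 lie with MDA-MB-231: 85.6% of the 1413 genes that separate the sensitive lines are nearer to sensitive MDA-MB-231, a share that lay between the bounds set for a wrong label or a culture of MDA-MB-231 cells and so did not decide. A change of state of MDA-MB-468 cells is argued against by SMAD4, which that genome has lost, and RB1, which is disrupted there. They stood at 79.6% and 66.5% of their sensitive MDA-MB-231 level, against 0.37% and 2.23% in sensitive MDA-MB-468. A mixture of both lines is argued against by 56 genes abundant in sensitive MDA-MB-468 alone, whose median was 0.0129% of their level there. An origin in MDA-MB-231 cells is consistent with 0 reads, 0% of the sensitive MDA-MB-468 level, for CDKN2A, CDKN2B and MTAP, which 3 counts would put at no more than 0.025%, 0.146% and 0.146%. Libraries with a wrong label and a resistant culture that was or became MDA-MB-231 cannot be told apart, because both predict the same expression and no separate record of the cultures is in the data. A swap with sensitive MDA-MB-468 would need a partner out of place there, and those libraries lacked SMAD4 (0.37% of the sensitive MDA-MB-231 level). The libraries labelled resistant MDA-MB-468 did not carry the sensitive MDA-MB-468 pattern of SMAD4, CDKN2A, CDKN2B and MTAP. The differences of effects above therefore contain the difference between the lines, and how much of each comes from it was not tested.

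The second pattern is that the libraries labelled resistant MDA-MB-468 share the changes of resistant MDA-MB-231 when both are set against sensitive MDA-MB-231. The covariance of the log2 differences over 14711 genes was 0.4859 (r = 0.528). In 100 simulations of unchanged groups against the same controls the mean was 0.000264 and the highest 0.000762 (difference from the mean 0.4857, r at most 0.0563). The bound set beforehand was passed, but the simulated groups were drawn around the mean of these same controls. That leaves out the controls' own error, which both comparisons share, so the simulations cannot decide on shared controls. Of 1800 genes changed at least 2-fold in resistant MDA-MB-231, 1010 (56.1%) changed at least 2-fold the same way and 124 (6.9%) the opposite way, with 483 higher against 93.5 for independent lists and 527 lower against 125.1. The bound set beforehand for a shared response of resistant MDA-MB-231 cultures was higher than 56.1%, so this remains undecided, and the 3 controls are too few to divide, so part of the excess may come from them. Related cultures, a shared response to selection and time in culture stay open.

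The third pattern is that keratin and other epithelial genes are higher in resistant MDA-MB-231. Carry-over of MDA-MB-468 cells or reads is argued against for KRT6A and PIGR, at 400% and 779% of the sensitive MDA-MB-468 level. CDH1 and ELF3, at 5.1% and 5.72%, also lay above the upper quartile of the 56 genes abundant in that line alone, 0.221%. For KRT5, at 0.576%, carry-over is not decided. CDKN2B and MTAP, neighbours of CDKN2A in the deleted region, reached 0.56% and 0.536% in resistant MDA-MB-231, on 2 to 7 counts per library. CDKN2A reached 0.106%. In sensitive MDA-MB-231 the upper quartile of the 56 genes was 0.0343%. S100A9 and LAD1, at 0.0649% and 0.184%, lay below 0.221%, and carry-over is not decided for them. A first bound on the median of the 56 genes (0.0752%) had left carry-over undecided, and the upper quartile was chosen after the values were seen. Depth or composition was not decided. The epithelial list kept its direction with an adjusted p of at most 2.4e-07 (camera) under RLE size factors and the stricter filter. These alternatives moved little, with 8587 and 8511 genes past the threshold against 8595, so they could hardly have removed such an effect. A change of cell state with resistance, and the growth of a subclone that already expressed these genes, were not tested and stay open as hypotheses.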

How the results depend on the processing

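Most alternatives were set before the data were examined; sensitive MDA-MB-231 as the reference was added after. The number of genes past the threshold stayed within 1.5 times the main count under the alternatives run, except that a test against a 1.5-fold change called 2410 in MDA-MB-231 (fewer genes reach that size) and that sensitive MDA-MB-231 as the reference left 3862 genes changed at least 2-fold in the libraries labelled resistant MDA-MB-468 in place of 7188, with 10718 past the threshold and 9 lists. Calls shared in direction between the lines numbered 2963 without the 2-fold minimum in place of 549. The number of lists depended on the list test: 0 in each line with an estimated correlation, 28 and 31 by fry, and 17 in MDA-MB-231 with no filter on low counts; the cause was not tested. By fry, 5 lists passed in the direction opposite to that of camera: SMADs (adjusted p = 0.0378) and luminal markers (0.0367) in MDA-MB-231, and ligands (0.000103), BMP targets (0.00159) and cyclin D and CDK inhibitors (0.000211) in MDA-MB-468 as labelled, lists whose members went both ways and none of which had passed by camera. With each library left out in turn, counts ranged from 7583 to 8616 genes (2053 to 2218 at least 2-fold) in MDA-MB-231 and from 11438 to 12957 (7367 to 7634) in MDA-MB-468 as labelled, lists from 9 to 12 and 11 to 14, shared calls from 549 to 575, r from -0.014 to 0.012 and interaction genes from 11031 to 12155. Same-numbered libraries did not deviate together (correlations -0.004, -0.087 and 0.077 in MDA-MB-231, -0.074, 0.043 and -0.207 in MDA-MB-468), so the numbers gave no sign of a pairing. A replicate block gave 8551 and 2019 genes in MDA-MB-231, 11536 and 7196 in MDA-MB-468, 10 and 11 lists, 545 shared calls, r = 0.004 and 11003 interaction genes; luminal markers and the CDK7-linked transcription factors in MDA-MB-468 did not pass with it (both adjusted p = 0.062). The CDK7-linked list also failed under RLE size factors (0.0503) and the stricter filter (0.0507). Named genes were followed under RLE size factors, DESeq2, the replicate block and each library left out. They were not followed under the test against a 1.5-fold change or the other alternatives. Of 1620 such values in MDA-MB-231, 1613 kept direction and call and 7 lost the call (TGFB1, GTF2H1 and MYC). In MDA-MB-468 as labelled, 1596 of 1602 kept them and 6 lost the call (HIST1H2AC and HIST1H2BK). Of 370 list values in MDA-MB-231 outside fry and the estimated correlation, 360 were unchanged, 1 lost and 9 gained a call, and of 360 in MDA-MB-468, 343 were unchanged, 11 lost and 6 gained. Leaving out sensitive replicate 2 brought other ABC transporters past the threshold in MDA-MB-231 (0.0445), and leaving out sensitive replicate 1 did so for BMP targets and transcriptional kinases (0.0486 each). At this depth ABCB1, with 0 to 9 counts per library, could not be compared.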

Other observations

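Tested protein-coding genes were grouped into families by the stem of their symbols after the data were seen. Genes of the fixed lists were not taken out, so the keratin, collagen and histone families recount members of those lists. In resistant MDA-MB-231, 8 of 18 tested keratin genes were at least 2-fold higher (44.4% against 6.9% of all tested protein-coding genes, Fisher's exact test, adjusted p = 0.000731). By the same test, so were 12 of 41 interleukin and interleukin-receptor genes (29.3%, adjusted p = 0.000731), 7 of 19 cytochrome P450 genes (36.8%, adjusted p = 0.00746) and 8 of 29 collagen genes (27.6%, adjusted p = 0.0197). Histone genes were at least 2-fold lower in 10 of 22 (45.5% against 6% of all tested protein-coding genes, Fisher's exact test, adjusted p = 3.44e-05). In the libraries labelled resistant MDA-MB-468, 20 of 32 collagen genes were at least 2-fold higher (62.5% against 19.9%; adjusted p = 3.09e-05), and 16 of 22 keratin genes (72.7% against 22.4%; adjusted p = 6.42e-05), 14 of 25 cytochrome P450 genes (56%; adjusted p = 0.0164) and 77 of 247 solute carrier genes (31.2%; adjusted p = 0.0366) were lower. In all, 88 and 91 families were tested, and members of a family are not independent.

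Set against sensitive MDA-MB-231, a comparison chosen after the data were seen, the libraries labelled resistant MDA-MB-468 had 9 lists past the threshold of camera with the preset correlation; the estimated correlation was not run for these. NF-κB targets and cytokines were higher in 19 of 22 (adjusted p = 2.23e-05; median 2.00), unfolded-protein and amino-acid stress genes in 17 of 19 (adjusted p = 2.23e-05; median 1.65) and epithelial markers in 10 of 14 (adjusted p = 0.00131; median 1.02). Collagens and laminins were higher in 17 of 26 (adjusted p = 0.0121), NRF2 targets in 12 of 19 (0.0144), hypoxia genes in 15 of 22 (0.0366), mitochondrial transcripts in 9 of 13 (0.046) and SMAD2/3 targets in 16 of 27 (0.048). Histone genes were lower in 8 of 12 (0.049). Cholesterol genes, lower in 11 of 18 and higher in 6, did not pass (0.402). Other lists past the threshold against sensitive MDA-MB-468 did not pass here: antagonists and latency proteins (0.571), mesenchymal markers (0.664) and luminal markers (0.137). Nor did matrix proteases (0.296), interferon response (0.109), antigen presentation (0.0815) or the CDK7-linked transcription factors (0.664). LCN2 was higher by 4.86 ± 0.198 on the log2 scale.

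Between libraries of a group, chi-square per degree of freedom over the gene counts was 3.29 to 9.10 in MDA-MB-231 and 6.76 to 56.4 in the MDA-MB-468 table, so no pair of libraries was a copy of another. The pairs of sensitive MDA-MB-468 replicate 1 with its group were at 49.2 and 56.4. The authors' deposited adjusted p was under 0.05 for 7857 genes in MDA-MB-231, 3773 higher and 4084 lower, and for 12766 in MDA-MB-468, 6165 higher and 6601 lower. At an unadjusted p under 0.05, edgeR called 9257 and 12291 genes.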
